A study of Halobacterium salinarum NRC-1 with 52 samples.

How the data were processed

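The samples were total RNA from Halobacterium salinarum NRC-1 cultures and a mid-log reference of the same strain, labelled with Alexa 532 and Alexa 647 and hybridised in both dye orientations, per the labels. The deposited scanner files held, per the file headers, the mean intensity of each spot and the median and standard deviation of its local background, at a high and a low scanner setting for each dye, with no background correction. The headers name the dye that the labels call Alexa 532 by another number, and the direction of each ratio follows the labels. The software and settings were not given in the sources used here. The authors' deposited value table held a log10 ratio per spot. Set against the scanner values of the same arrays, it ran as culture over reference on arrays of both orientations, with a slope of 0.248 to 0.307 on the log2 ratio and a correlation of 0.764 to 0.996 over the brightest spots. It was not centred on 0, with array medians from 0 to 0.18 with the culture in Alexa 532 and from -0.0726 to 0.0676 in Alexa 647, and each array held between 12 and 4930 spots at exactly 0. How those values were normalized was not given in the sources used here.

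Log ratios were computed from the high scanner setting with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, arrays were normalized within themselves by loess, and arrays with the culture in Alexa 532 had their sign turned, so that every ratio is culture over reference. No pair of arrays of 1 orientation correlated below -0.3 (lowest r = 0.0124 over 650 pairs), and no 2 arrays held identical values (highest r = 0.926). Each array had 10752 spots. Neighbouring spots and a copy in the other part of the array carried the same probe set (r of mean log2 intensity, 0.995 and 0.966), and the 4 spots were averaged. The platform table gave 1 gene symbol for 532 spots, that is for 133 probe sets, several symbols for 0 and none for the other 2555 probe sets. These symbols can be old, and no coordinates are given because the annotation at hand was of another strain. Cross-hybridisation between related genes, such as gdhA1 and gdhA2 or the htr genes, was not assessed, so their values are uncertain.

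A replicate value was the mean over dye orientations of 1 OD label in 1 run of array numbers. Arrays at OD 4.860, of which each run had 4, were averaged likewise. The labels do not state which array belongs to which culture, so the run stands for the biological replicate, and p-values measure the spread between these values. Both runs carry the same OD labels. If the runs were repeat hybridisations of the same samples, each label would have 1 biological sample and the p-values at single labels would cover technical spread only. The fit of classes took all 24 values as independent. If the labels of a run were samples of 1 culture, they would not be independent, and the class contrasts would rest on 2 cultures. The SEs and p-values of the class contrasts could then be too small. Labels were grouped before the data were examined into low (6 labels, 12 values), intermediate (3 labels, 6 values) and high density (3 labels, 6 values). Contrasts of classes, the F test over 12 labels, the 11 consecutive steps and the interaction with run were fitted with lmFit and eBayes, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Gene lists were tested with camera at its preset correlation, and again with an estimated one. Of 23 lists fixed before the data were examined, 14 had a named member and 8 had the 3 members needed for a test. The symbols glmS and panB were taken out of lists whose pattern they matched by accident or without certainty. A further 7 lists were added after the symbols, but before any value, had been seen.

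Genes were named by a rule fixed before the data were examined. It took the 6 highest and 6 lowest named changes of each class contrast among genes called and of the same sign in both runs, the called member of each list with the largest absolute change, with up to 3 members for the 6 lists with the lowest camera p, the 3 highest and 3 lowest of the step with most calls, and the 3 lowest p of the interaction. Genes named outside this rule were chosen after their values were seen. A probe set was well above background on an array where 2 or more of its 4 spots exceeded the background median by 2 background standard deviations. For called genes without such an array in a class, a lower bound of the fold was computed from the channel levels after loess and Aquantile, and no fold is given where that bound was not above 1 or where neither class had such an array. For steps between labels, no fold is given for a gene without such an array at a label. Spots at an intensity of 60000 or more were taken as near the ceiling.

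The procedure was tested on simulated values with each probe set's spread within OD labels, drawn independently. For high against low density, over 2688 probe sets, 84% of 50 log2 changes of 0.5 and 100% of 50 changes of 1 were recovered, with 4.95% false calls. The simulated labels of a class did not differ from each other, while in the real class fit such differences count as spread. Recovery in the real class contrasts can therefore be lower, and their rate of false calls was not measured. For the step from OD 0.590 to OD 0.710, 16% of changes of 0.5 and 84% of changes of 1 were recovered. Run was not a term in the class models, a choice fixed beforehand, and a block for run was an alternative. The run difference at 1 OD label correlated above 0.1 with that at another in 43 of 66 pairs of labels (median r = 0.153, across probe sets). Alternatives changed the background correction, the normalization, the filter on dim probe sets, the use of dyes and spots, the pairing of OD 4.860 arrays, the block for run, the classes and the replicate values left out. Alternatives added after the data were seen were scaling between arrays, the centred value table, the low scanner setting, leaving out OD 0.710 and OD 0.762 or ordering them by array number, and leaving out 2 arrays numbered outside their run's order. The low scanner setting was run first with normexp, which reached its numerical limit in 34 of 104 channels. Up to 79.2% of the spots of a channel were at 0, and that version called 0 probe sets in each class contrast by limma, with 49, 66 and 5 at an unadjusted p under 0.05. A version without background correction was then chosen and is the one reported.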

Results

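Transcript levels of the haloarchaeon Halobacterium salinarum NRC-1, an extreme halophile that lives near salt saturation, were measured along a growth curve in rich medium under constant light. Cultures were sampled at 12 optical densities from OD 0.259 to OD 5.640, and the RNA of each sample was hybridised against RNA of a mid-log reference culture (OD600 0.5 to 0.6) on 52 spotted arrays of 2 colours. Each OD label had 4 arrays, except OD 4.860 with 8, and the culture RNA carried Alexa 532 on 26 of the 52 arrays and Alexa 647 on the others. The array numbers fell into 2 runs, taken as the 2 biological replicates that the series describes, so each OD label had 2 replicate values and the series had 24. Both runs carried the same OD labels to the last decimal. The 2688 probe sets were each printed as 4 spots, and 133 of them could be named by a gene symbol. The other 2555 are counted but not named here, and may include controls. On the median array 20.9% of probe sets were well above background in the culture channel, with a range from 7.59% to 56.4%. The number of arrays limits the precision of every value.

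The first question was how transcript levels at high density differ from those at low density. High density was OD 4.860 to 5.640 and low density OD 0.259 to 0.803. The ribosomal protein gene rpl12p fell by 1.10 ± 0.21 on the log2 scale (SE of the fit, 6 high and 12 low values, adjusted p = 0.00032), and rpmC, the symbol of another ribosomal protein, fell by 0.87 ± 0.21 but did not pass with scaled log ratios (log2 change -0.64, adjusted p = 0.0567). The succinyl-CoA synthetase genes sucD and sucC fell by 0.94 ± 0.16 and by 0.91 ± 0.17. The cobaltochelatase gene cobN fell by 0.95 ± 0.08 (adjusted p = 2.39e-08). The highest rises among named genes were those of hop, which encodes the light-driven chloride pump halorhodopsin, with a log2 change of 0.72 ± 0.14, of the ferritin-like gene dpsA with 0.68 ± 0.23, and of the glutamate dehydrogenase gene gdhB with 0.64 ± 0.15. Of these genes, hop was not well above background on any array at OD 0.590, OD 0.710 or OD 0.762, and was on 2 arrays at OD 0.803. The size of its change is therefore uncertain. The transducer gene htr8 rose by 0.60 ± 0.09. The argininosuccinate lyase gene argH had a log2 change of 0.61 ± 0.25, and its adjusted p of 0.0476 rose above 0.05 without any 1 of several replicate values, reaching 0.113 without OD 5.640 of run 1, while its change was 0.20 without OD 0.259 and OD 0.364 (adjusted p = 0.382). The rise of dpsA did not pass without OD 4.860 (adjusted p = 0.0758), without OD 0.259 and OD 0.364 (log2 change 0.35), in either run alone, with scaled log ratios, at the low scanner setting or in the centred value table, where gdhB did not pass either. In run 1 alone gdhB did not pass (log2 change 0.57, adjusted p = 0.0703).

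In the list of tRNA synthetases, the enzymes that load amino acids onto tRNAs, 8 of 12 members fell, none rose and 4 did not pass the test. With scaled log ratios 4 of the 12 fell, and 6 did in the deposited value table, centred or not. The list was shifted down by the camera test (adjusted p = 0.00484), and 10 members fell when adjusted over the list alone. Camera sets a list against all other probe sets, most of them unnamed. Named genes as a whole fell in 40.6% and unnamed probe sets in 23.4%. Here and in the other lists that fell, a fall shared by named genes is not told apart from a fall of the list itself. The lysine, proline and serine enzymes lysS, proS and serS fell by 0.70 ± 0.17, by 0.70 ± 0.15 and by 0.68 ± 0.12. In run 1 alone proS fell by 0.38 and did not pass (adjusted p = 0.105), nor did it with 1 mean per run and class (0.0541), and lysS did not pass in run 2 alone (0.0606). In the citric acid cycle list 4 of 6 members fell, the malate dehydrogenase gene mdh by 0.65 ± 0.16 and the isocitrate dehydrogenase gene icd by 0.32 ± 0.07 among them, while sdhC and citZ did not pass. The call of mdh ended with median centring (adjusted p = 0.136). Its camera adjusted p was 0.00484, and 5 members fell when adjusted over the list alone. In the cobalamin synthesis list cobN, cbiT and cbiG fell and cbiQ did not pass (camera adjusted p = 0.00484, and 3 members when adjusted over the list alone). The fall of cbiT was 0.86 ± 0.10, and that of cbiG was 0.25 ± 0.09, a call that ended without OD 5.130 of run 1 (adjusted p = 0.0858) or of run 2 (0.0675), and in 6 other settings, with a change of -0.13 when scaled (0.393) and -0.18 in run 2 alone (0.408). With an estimated correlation between genes, none of these 3 lists was called (adjusted p = 0.275 for each list with an estimated correlation, 1 of 8 lists at an unadjusted p under 0.05).

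The 5 other lists with at least 3 members were not shifted by camera. The numbers that rose and fell in these lists were the same when adjusted over the list alone. In the chemotaxis and transducer list 4 of 11 members rose and 1 fell (adjusted p = 0.41), with a median log2 change of -0.0167 and a mean of 0.0641, so that median and mean differed in sign. With median centring 2 rose and 4 fell. The members htr18 and htr4 passed the test, but they were not well above background on any array of either class, so no fold is given for them. The call of htr4 ended without background correction (adjusted p = 0.0571) and its sign turned in the deposited value table (0.606), and that of htr18 ended with Alexa 532 alone (0.0586) and in run 1 alone (0.105). In the rhodopsin and carotenoid list 1 of 4 members, hop, rose (adjusted p = 0.353). In the nucleotide synthesis list 3 of 12 members fell (adjusted p = 0.286), against 5 that fell and 1 that rose with median centring and 2 of each in the value table. The aspartate carbamoyltransferase regulatory gene pyrI fell by 0.47 ± 0.09, but did not pass in run 2 alone (log2 change -0.41, adjusted p = 0.0618). The genes carB and purL also passed, but were not well above background on any array of the high class and have no fold. The call of carB ended in the deposited value table (adjusted p = 0.3), in the centred table (0.127), at the low scanner setting (0.406) and in run 2 alone (0.0555). The call of purL ended without OD 5.130 or OD 5.640 of run 2 (adjusted p of 0.08 and 0.119), in run 1 alone (0.262) and with 1 mean per run and class (0.291). It also ended with Alexa 532 alone (0.429), in the deposited value table (0.415) and in the centred table (0.165). With scaled log ratios (0.23) and at the low scanner setting (0.997) purL did not pass either. Of the chaperone and protease list 1 of 5 members fell, the heat shock protein gene dnaK by 0.67 ± 0.13 (adjusted p of the list, 0.576). Of the DNA replication and repair list 1 of 8 members rose and 1 fell, the gyrase gene gyrA by 0.42 ± 0.14 (adjusted p of the list, 0.836). The call of gyrA ended without OD 4.860 (adjusted p = 0.0745), without OD 0.259 and OD 0.364 (0.0893), in each run alone (0.125 and 0.145), in the deposited value table (0.0681), when scaled (0.0501) and at the low scanner setting (0.0544).

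Lists with fewer than 3 named members were not tested as lists. The only named member of the respiratory chain list, nuoL, fell by 0.25 ± 0.07, but did not pass in run 2 alone (log2 change -0.15, adjusted p = 0.293), with 1 mean per run and class (0.126) or with Alexa 647 alone (0.0584). The only one of the phosphate uptake list, phoU, fell by 0.72 ± 0.14, but by 0.07 at the low scanner setting, where it did not pass. The arginine deiminase gene arcA rose by 0.40 ± 0.13, but its change was 0.02 with median centring and -0.05 in the centred value table, neither of which passed, while arcC had a log2 change of 0.25 ± 0.18 that did not pass. The call of arcA also ended in each run alone (adjusted p of 0.127 and 0.124), in the uncentred value table (0.906) and with scaled log ratios (0.0829). It ended at the low scanner setting (0.12) and without OD 0.710 and OD 0.762 (0.0932) too. Both members of the oxidative stress list rose, dpsA and the methionine sulfoxide reductase gene msrA, the latter by 0.40 ± 0.09. The surface glycoprotein gene csg had 2 or more of its 4 spots near the scanner's ceiling on 18 of 24 low, 4 of 12 intermediate and 10 of 16 high arrays. It has no settled direction here. The gene hutG was among the 6 highest changes, but was not well above background on any low or high array.

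**Figure D1:**
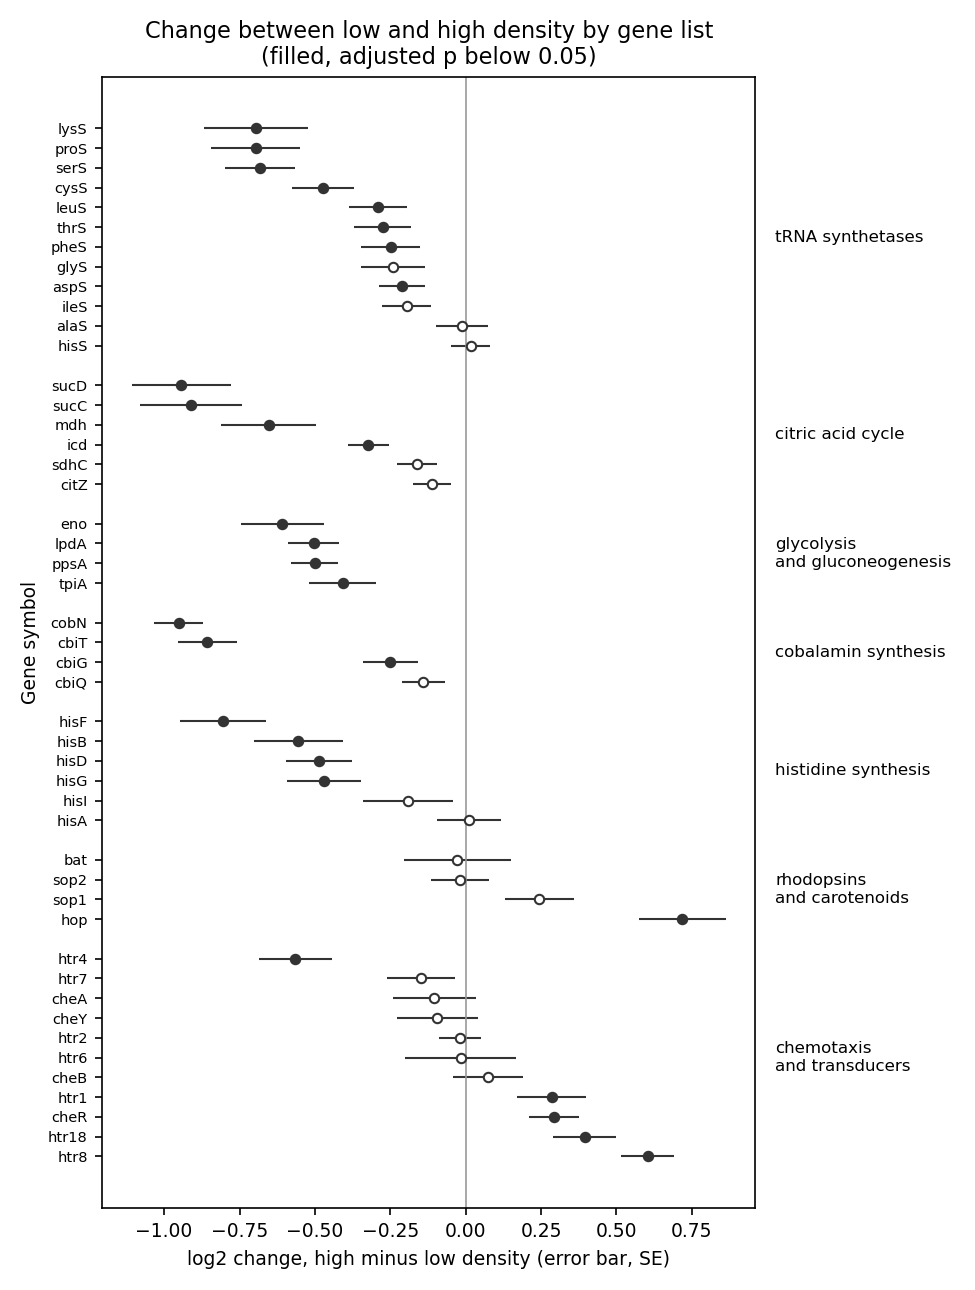
Log2 change from low to high density for the named members of 7 gene lists, with the SE of the fit as error bars. Filled points passed adjusted p below 0.05 and open points did not; htr4, htr18, hisB, hisD and hisG were not well above background on any high array and their folds are not read. All 8 called tRNA synthetases and all 4 called citric acid cycle genes lie to the left of 0, and hop, dim at several low labels, lies at 0.72.

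In all, 1193 of 2688 probe sets differed between high and low density (limma, adjusted p below 0.05), 541 higher and 652 lower at high density. The share that rose was 45.3%, but 60.9% in the deposited value table (44% once centred) and 51.3% with median centring, so the majority direction is not settled. Of these, 76 changed by 2-fold or more, 64 of them upward. Among the 133 named genes 14 rose and 54 fell. The sign was the same in both runs for 1190 of the 1193, but these were selected on the 2 runs together, which favours a shared sign. Over all probe sets the changes of the 2 runs correlated at r = 0.835, genes not being independent replicates. Each class mixes OD labels, whose values the fit took as independent within a run. With 1 mean per run and class 560 probe sets were called, with 488 in run 1 alone and 656 in run 2 alone. The count was 682 with log ratios scaled between arrays, 785 without OD 0.259 and OD 0.364, 466 at the low scanner setting and 771 in the authors' deposited value table after centring.

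The same question was asked of intermediate density, OD 1.329 to 3.510. The largest rise among named genes was that of dpsA, with a log2 change of 1.02 ± 0.23 (6 intermediate and 12 low values, adjusted p = 0.00148). This rise did not pass at the low scanner setting (log2 change 1.115, adjusted p = 0.0804). Behind it came the thiamine synthesis gene thiD with 0.79 ± 0.24, hop, dim at several low labels, with 0.76 ± 0.14 and gdhB with 0.71 ± 0.15. The genes with the lowest changes were rpmC, which fell by 0.97 ± 0.21, rpl12p, which fell by 0.93 ± 0.21, sucC, which fell by 0.90 ± 0.17, and sucD, which fell by 0.89 ± 0.16. The histidine synthesis gene hisF and carB passed with falls too, but neither was well above background on any intermediate array, nor was bat, the bacterio-opsin activator gene, on any array of either class, so these 3 have no fold. The call of bat ended in each run alone (adjusted p of 0.0528 and 0.186), with 1 mean per run and class (0.0593) and with Alexa 647 alone (0.0653). It also ended with scaled log ratios (0.093), in the centred table (0.0658) and at the low scanner setting (0.267). The rise of thiD did not pass with median centring (adjusted p = 0.121), in either run alone (0.115 and 0.101) or with scaled log ratios (0.188), and that of gdhB did not with median centring (0.167). Neither passed at the low scanner setting (0.244 for thiD and 0.0766 for gdhB) or in the centred value table (0.0748 and 0.0738). The call of carB ended without OD 3.510 of run 2 (adjusted p = 0.0666), in each run alone (0.117 and 0.0602) and with 1 mean per run and class (0.0811). It also ended in the deposited value table (0.201), in the centred table (0.0948) and at the low scanner setting (0.387). The gene csg passed too, but with spots near the scanner's ceiling on 18 of 24 low and 4 of 12 intermediate arrays its change is not given, and its sign differed between settings.

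By list, 8 of 12 tRNA synthetases fell at intermediate density (camera adjusted p = 0.00459), as did 4 of 6 citric acid cycle genes (adjusted p = 0.00744) and 2 of 4 cobalamin genes (adjusted p = 0.0448). In the chemotaxis and transducer list 5 of 11 members rose and 1 fell (adjusted p = 0.0482), with the methyltransferase gene cheR at 0.41 ± 0.08 and the methylesterase gene cheB at 0.38 ± 0.12. None of these 4 lists was called with an estimated correlation (adjusted p of 0.316 for the first 3 and 0.323 for chemotaxis with an estimated correlation). The numbers of members that rose or fell were the same when adjusted over the list alone. Of the lists that were not shifted, chaperones and proteases had 2 of 5 members that fell (adjusted p = 0.0992), DNA replication and repair 2 of 8 (0.296), and nucleotide synthesis 2 of 12 (0.304). In the rhodopsin list 3 of 4 members rose, sop1, the gene of sensory rhodopsin I, by 0.43 ± 0.11, with a list adjusted p of 0.0872. A total of 964 probe sets differed, 459 higher and 505 lower. The share that rose was 47.6%, but 56.2% with scaled log ratios, 55.1% and 57.7% in each run alone, 53.4% in the value table (41.9% once centred) and 86.6% at 2-fold or more, so the majority direction is not settled. Among the calls were 62 named genes, 14 higher and 48 lower. The count was 510 with 1 mean per run and class, 450 and 515 in each run alone, 557 with scaled log ratios, 453 at the low scanner setting and 1699 with median centring in place of loess.

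Between intermediate and high density no named gene passed the test. The named genes with the lowest unadjusted p were ppsA, the phosphoenolpyruvate synthase gene, with a log2 change of -0.36 ± 0.09, and cobN with -0.35 ± 0.09, both chosen after their values were seen. The changes of rpl12p, hop and sucC, all called against low density, were -0.17 ± 0.25, -0.04 ± 0.17 and -0.01 ± 0.19. These SEs rest on a spread pooled over the 3 classes, the low class included. Label means of rpl12p lay from -1.45 to -1.53 at intermediate and -1.53 to -1.76 at high density. At low density they lay from 0.151 to -1.33, so the SE does not measure the spread within the 2 classes compared. Of the 2688 probe sets 12 were called by limma, 10 higher and 2 lower at high density, and 270 had an unadjusted p under 0.05. Of the 8 tested lists, cobalamin synthesis was lower at high density (camera adjusted p = 0.015), and not with an estimated correlation (adjusted p = 0.371 with an estimated correlation), while the lowest adjusted p of the other lists was 0.149. No member of the cobalamin list passed over all probe sets, and 1 fell when adjusted over the list alone. The count was 3 with median centring, in the deposited value table and with the culture in Alexa 647 alone, 2 in each run alone, and 1 at the low scanner setting.

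Each OD label was then compared with the next lower one, to see between which densities transcripts moved. The step from OD 0.590 to OD 0.710 had the most calls in the order of the OD labels, 397 probe sets, 175 higher and 222 lower. In the order of the array numbers, in which OD 0.762 precedes OD 0.710, the most calls were 264, from OD 0.762 to OD 0.710, with 1 from OD 0.590 to OD 0.762. From OD 0.590 to OD 0.710 the highest named changes were those of dpsA with 0.97 ± 0.17, hop, and the carbamate kinase gene arcC with 0.55 ± 0.17. The lowest were those of carB, pan1, the proteasome-activating nucleotidase gene, and sucC, which fell by 1.105 ± 0.131. No fold is given for hop, which was not well above background on any array of the 2 labels, or for carB and pan1, which were not on any array at OD 0.710. The call of carB ended in the deposited value table (adjusted p = 0.127). None of the 3 rises passed with median centring, where dpsA had a log2 change of 0.46 (adjusted p = 0.0508), hop an adjusted p of 0.102 and arcC a change of 0.06 (0.836). The calls of hop and arcC also ended in the deposited value table (0.0926 and 0.45) and without single values, for example OD 0.590 of run 2 (0.138 and 0.0856). From OD 0.710 to OD 0.762, 264 probe sets changed, and sucC rose by 0.76 ± 0.13 while dpsA fell by 1.12 ± 0.17. From OD 0.762 to OD 0.803, 224 changed, and sucC fell again, by 0.66 ± 0.13.

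Earlier, from OD 0.364 to OD 0.590, 121 probe sets changed, 95 of them upward, and 13 named genes were among them. From OD 0.803 to OD 1.329 only 11 changed, with dpsA rising by 1.26 ± 0.17 while the phosphate regulator gene phoU passed with a fall, without a fold since it was not well above background on any intermediate array. No probe set passed limma's adjusted test from OD 0.259 to OD 0.364 or at the 5 steps above OD 1.329, where 40 and between 62 and 205 probe sets had an unadjusted p under 0.05. At least 1 of the 11 steps was called for 505 probe sets, 39 of them named, and 354 were called when OD 0.710 and OD 0.762 were put in the order of the array numbers. The count was 246 in the deposited value table and 263 with the culture in Alexa 532 alone. Over all 12 labels the F test called 1005 probe sets, 79 of them named, rpl12p with an adjusted p of 7.46e-09 and thiD with 6.22e-08 among them.

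**Figure D2:**
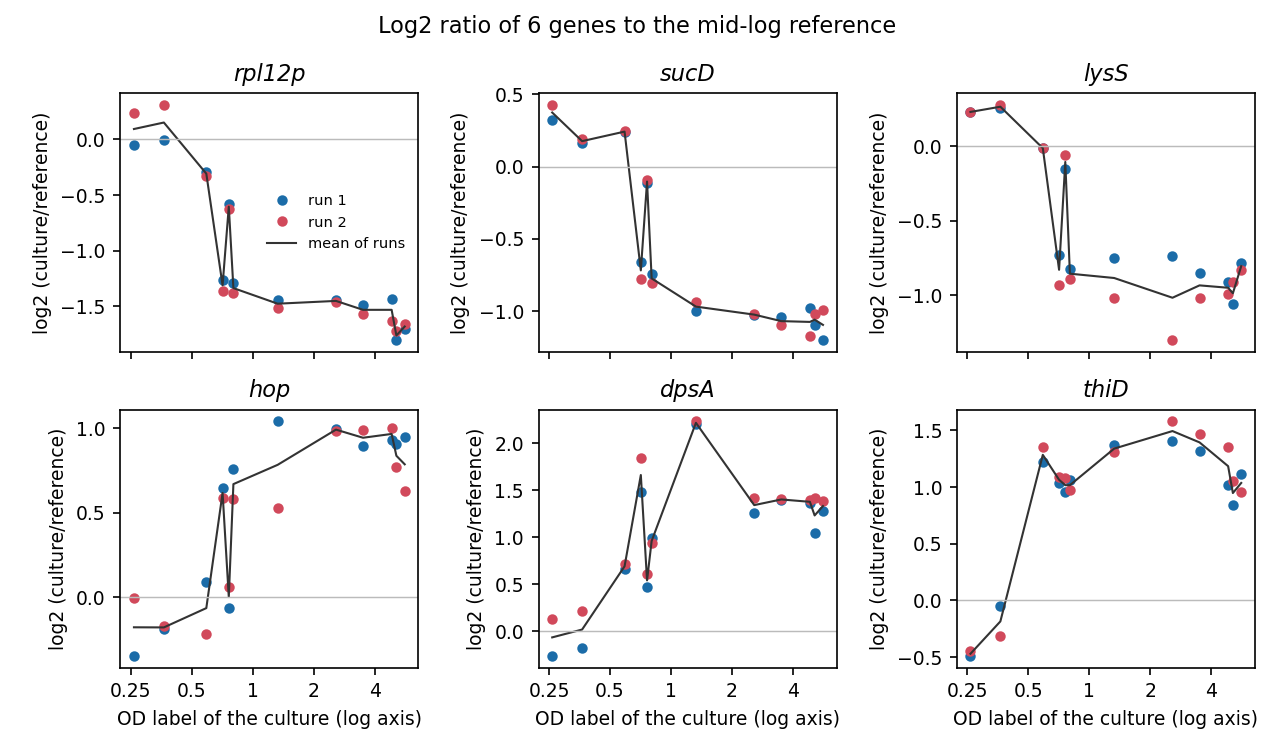
Log2 ratio of 6 genes to the mid-log reference against the OD label on a log axis, with 1 point per run and a line through the mean of the runs. The ribosomal gene rpl12p and the succinyl-CoA synthetase gene sucD fell between OD 0.590 and OD 0.710 and stood higher again at OD 0.762, while thiD had reached its later level by OD 0.590.

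The distance of each culture from the reference was taken as the median absolute log2 ratio over probe sets. It was 0.163 ± 0.0433 at OD 0.364 and 0.179 ± 0.047 at OD 0.259 (SD, n = 2 runs), and 0.238 ± 0.00963 at OD 0.590, the label closest to the stated reference density. It was 0.350 ± 0.0904 at OD 0.710, 0.230 ± 0.0385 at OD 0.762 and 0.293 ± 0.0039 at OD 0.803. From OD 2.580 upward the means lay between 0.403 and 0.434, with SDs up to 0.133. No test was run on these distances.

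**Figure D3:**
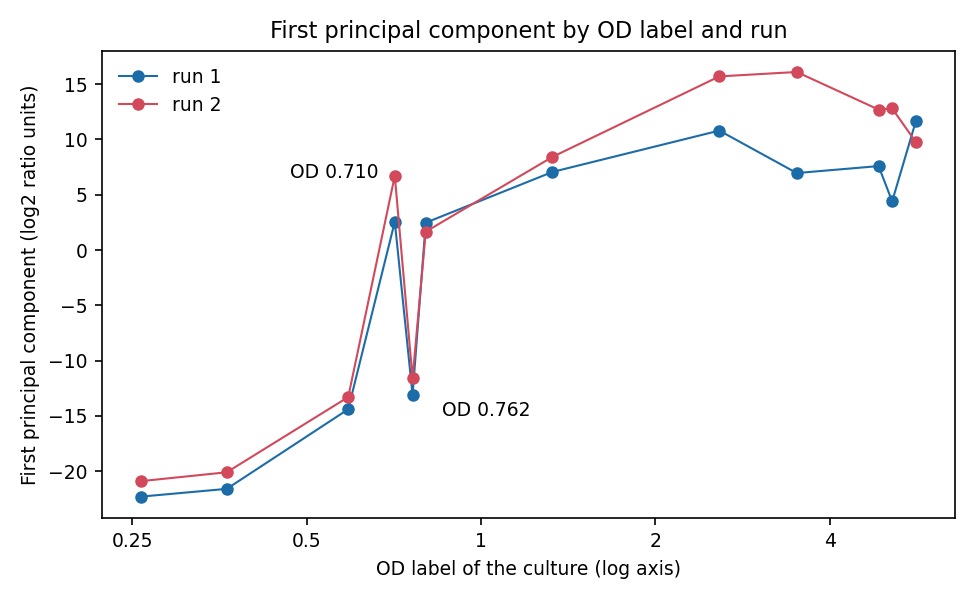
First principal component of the 24 replicate values, in log2 ratio units, against the OD label on a log axis, with a line per run. OD 0.762 lies at -13.1 and -11.6 (run 1 and run 2), near OD 0.590 at -14.4 and -13.3. OD 0.710 lies at 2.56 and 6.71, against 2.47 and 1.66 for OD 0.803. It is near OD 0.803 in run 1, while in run 2 it lies nearer OD 1.329 at 8.42.

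The first principal component held 55.4% of the variance and the second 8.78%. Whether the 2 runs gave the same change from low to high density was tested by the interaction of run and class. No named gene differed between runs. The lowest p-values among named genes belonged to tmk, hisB and proS, none of which passed. Of all probe sets 5 differed by limma, none of them named, and 190 had an unadjusted p under 0.05. The count was 3 with median centring and 0 in the deposited value table.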

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

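The 2 tests of the OD 0.710 and OD 0.762 pattern and the test of named genes over normalizations, the interval for signal in the high class, and the splits by run, were chosen only after the result was seen.

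At OD 1.329 of run 2, 5 genes stood apart from the other 5 values of the intermediate class. The log2 ratio of hop was 0.527 there against 0.896 to 1.04 in the others, and that of bat 0.288 against 0.878 to 1.19, although bat was not well above background on any low or intermediate array, so its values say little. For serS it was -0.555 against -1.06 to -0.878, for nuoL -0.084 against -0.403 to -0.286, and for pyrI -0.0487 against -0.726 to -0.538. The ratio of phoU was -0.238 at OD 2.580 of run 2 against -0.784 to -0.58. In the high class gdhB was 0.506 at OD 5.130 of run 1 against 0.857 to 0.909. These genes were far from the rest of their group by a gap test, in 7 of 72 groups of 6 values tested, and chance gives about 1 in 20.

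The change from low to high density differed between the runs for 5 probe sets, all unnamed. The largest differences were those of probe_2581, which changed by 0.22 in run 1 and 1.49 in run 2, and probe_2320, which changed by -0.19 and -1.39. Both were chosen after their values were seen.

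Transcript profiles did not follow the order of the OD labels between OD 0.590 and OD 0.803. A fault of single arrays or of 1 dye is argued against by all 4 sets of arrays (2 runs, 2 dye orientations), in each of which OD 0.762 lay nearer OD 0.590 and OD 0.710 nearer OD 0.803. On the 349 probe sets called between OD 0.590 and OD 0.803 alone, OD 0.762 lay at most 18.6% of the way in either run, and OD 0.710 at 95.6% and 109%. The array numbers place OD 0.762 before OD 0.710, and in that order limma called 1 probe set from OD 0.590 to OD 0.762, 264 from OD 0.762 to OD 0.710 and 0 from OD 0.710 to OD 0.803, with 103, 600 and 84 at an unadjusted p under 0.05. From OD 0.710 to OD 0.803 the first principal component went from 2.56 to 2.47 in run 1 and from 6.71 to 1.66 in run 2. Exchanged labels, or samples taken out of order of density, are a candidate explanation for the place of OD 0.762. It cannot be told apart from a true return of transcripts at OD 0.762, because both runs carry the same labels and the same order.

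Few probe sets differed between intermediate and high density. The fit pooled its spread over the 3 classes, so differences among the low labels entered the test of this contrast. A fit without the low class was not run. The smaller number of values is argued against for changes as large as those from low to intermediate density. Any 3 of the 6 low labels against intermediate density still called 319 or more probe sets in each of the 20 choices. For smaller changes it stays open, since 270 probe sets had an unadjusted p under 0.05 by limma. Weaker signal in the high class stays open: the median percent of probe sets well above background was lower by 1.57 points than in the intermediate class (difference -1.57, 95% bootstrap interval -7.06 to 12.5). A transcript state reached by about OD 1.3 and held afterwards is a hypothesis. These data do not separate it from weaker signal, from small changes missed with few values, or from the spread of the low class in the fit.

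Named genes fell more often than unnamed probe sets, 40.6% against 23.4% (Fisher's exact test, two-sided, p = 1.76e-05). The test took probe sets as independent, though all were measured in the same 24 values, so its p does not measure the spread between replicates. Unnamed probe sets may also include controls. The brighter spots of named genes account for part of the difference, since unnamed probe sets matched in intensity fell in 30.6% on average. Of 1000 matched draws, which also took probe sets as independent, 9 reached the named percentage. In 6 other normalizations at least 76.3% of named calls were falls, while 42.9% to 60.9% of all calls were rises. Named calls thus leaned further toward falls in each, which argues against normalization as the whole cause of that lean. The percent of unnamed probe sets that fell was not taken in these settings, so the difference in percent fallen was not tested there. The named symbols are no random sample of the genome, and whether their functions differ from those of unnamed genes could not be tested.

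Random regroupings of the same values were set against each count. The real density classes keep the 2 values of an OD label together, which the splits of classes did not have to do. Values of 1 label were alike across runs (r from 0.516 to 0.926), so the real classes were favoured beforehand. For high against low density 1 of 100 splits, the real one, gave 1193 or more calls, and the highest other gave 233. For intermediate against low density it was also 1 of 100, with 736 in the highest other. For high against intermediate density 4 of 100 splits gave 12 or more, and the highest other gave 156. Run is a structure of these 12 values, since parting them by run alone called 252. Of the 200 splits with 3 values of each run in each group, only the real one gave 12 or more and the highest other gave 2, and with run as a block 13 probe sets were called. Most of these 200 part the 2 values of a label, so they cannot exclude chance for a grouping of whole labels. For the difference between runs 4 of 100 gave 5 or more, with 23 in the highest other. For the 3 shifted lists 13 of 100 splits gave as many, with 5 in the highest other, so chance cannot be excluded for the count of lists.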

How the results depend on the processing

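The scaled log ratios, the centred value table, the low scanner setting and the order by array number were chosen after the data were seen, and the cause was not tested unless stated. Probe sets high against low (1193) became 560 with 1 mean per run and class, which takes the run as the unit, and 488 and 656 in single runs. Each of these counts also rests on fewer values. The count was 76 at 2-fold or more, 785 without OD 0.259 and 0.364, and 682 scaled. It was 771 in the centred table and 466 at the low setting, which also left out background correction. The share that rose was 45.3%, and 60.9% in the uncentred and 44% in the centred value table. Intermediate against low (964) became 510 with 1 mean per run and class, 450 and 515 in single runs, and 97 at 2-fold. It became 1699 with median centring, 557 scaled and 453 at the low setting. High against intermediate (12) became 3 with median centring, in the value table, with Alexa 647 alone and at 2-fold, 2 in either run, 6 in the centred table and 1 at the low setting; 83.3% rose, 100% when scaled, centred or median centred, 55.6% with 1 mean per run and class (9 calls) and 0% in run 2 alone (2 calls). The F test (1005) gave 664 in the value table and at the low setting, 653 centred and 1556 with a spline. Steps (505) gave 246 in the value table and 263 with Alexa 532 alone. Shifted lists (3) became 0 in limma's camera with an estimated correlation, 1 at an unadjusted p under 0.05. Differences between runs (5) became 3 with median centring and 0 in limma with the value table, Alexa 647 alone and the low setting, where 112, 292 and 66 had an unadjusted p under 0.05. High minus low distance from the reference, 0.173, was 0.107 without background correction, 0.231 with median centring and 0.141 in the value table. Of the values of genes named by the rule, over all settings, 1774 counted as unchanged, 138 lost the call and 6 reversed. The unchanged include values from leaving out single values and from Aquantile, so their number does not measure robustness to normalization. The 6 were csg (-0.57 and -0.63 in the value table and centred table, -0.38 at the low setting), htr4 (0.072, value table), arcA (-0.049, centred table) and purL (0.00071, low setting). Values counted as unchanged kept sign and side of the threshold, or had no call in the main fit and changed sign. With run as a replicate block the counts were 1291, 1040, 13, 1165, 593 and 3, changing no count by over 1.5 times; own label was the best match across runs for 6 and 7 of 12 labels. Leaving out single values gave 970 to 1378, 760 to 1111, 8 to 15, 882 to 1101, 349 to 530, and 3 lists. Aquantile leaves ratios unchanged by construction. Low signal over background limits dim genes.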

Other observations

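The first large change came earlier than the shift at OD 0.710. From OD 0.364 to OD 0.590, before the labels whose order is in doubt, the thiamine synthesis gene thiD rose by 1.47 ± 0.14 on the log2 scale (SE, 2 values per label, adjusted p = 3.42e-06 by limma). The thiamine gene thiC and the proteasome-activating nucleotidase gene pan1 passed with rises too, without a fold since neither was well above background on any array at OD 0.364. At the same step the arginine fermentation genes arcC and arcA fell by 1.09 ± 0.17 and by 0.73 ± 0.11, and the translation initiation factor gene infB fell by 0.92 ± 0.17. Single genes of this step were not followed through the alternative normalizations or replicate values. From OD 0.590 to OD 0.710, where they were, the change of arcC was 0.06 with median centring, against 0.55 in the main fit. The mean log2 ratio of arcA was 0.257 at OD 0.259, -0.541 at OD 0.590 and 0.325 at OD 5.640. These genes were chosen after their values were seen. The reference had a stated OD600 of 0.5 to 0.6, yet thiD had a log2 ratio to it of -0.185 at OD 0.364 and 1.29 at OD 0.590. The ratio of infB was -0.0108 and -0.929 at these labels. By median distance too, the reference lay nearer OD 0.364 (0.163 ± 0.0433) than OD 0.590 (0.238 ± 0.00963). So this step cannot be read as a change with density alone, and its cause was not tested.

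In the lists added after the symbols were seen, all 4 members of the glycolysis and gluconeogenesis list fell from low to high density (camera adjusted p = 0.0116, and adjusted p = 0.0815 with an estimated correlation). They were eno, which fell by 0.61 ± 0.14, ppsA, which fell by 0.50 ± 0.08, tpiA, and lpdA, the dihydrolipoamide dehydrogenase gene, which serves oxoacid dehydrogenase complexes rather than glycolysis itself. In the histidine synthesis list 4 of 6 members fell (adjusted p = 0.0533), but hisB, hisD and hisG were not well above background on any high array, and 1 of 6 fell in the value table, in the centred table and at the low scanner setting. The glutamate dehydrogenase genes went apart, with gdhA1 falling by 0.85 ± 0.14, gdhA2 by 0.37 ± 0.12, and gdhB rising. Of the vitamin and cofactor list 4 of 11 members fell (adjusted p = 0.172), of protein export 1 of 3, secY by 0.64 ± 0.11 (adjusted p = 0.259), of histidine degradation 1 of 3 rose (adjusted p = 0.279), and of other amino acid synthesis 3 of 9 rose and 2 fell (adjusted p = 0.899, median log2 change -0.0522 and mean 0.0202). Of these 7 lists none passed with an estimated correlation (lowest adjusted p = 0.0815).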
